A study of Bacillus subtilis with 12 samples.

How the data were processed

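Total RNA of Bacillus subtilis was compared on 2-colour microarrays, in which the cDNA of 2 strains carries different fluorescent dyes and is hybridised to 1 slide. The strains were wild type, a ugtP mutant, an mprF pssA ywnE triple mutant and a ugtP mprF pssA ywnE quadruple mutant. Each mutant had 4 arrays against wild type. On 3 of them the mutant carried Alexa Fluor 647 and wild type carried Alexa Fluor 555, and on the dye swap the dyes were exchanged. Per the labels' protocols, RNA was purified on columns, treated with DNase and copied to cDNA by indirect labelling. Per the series' design text, the 4 arrays of a mutant came from 3 independent RNA preparations, so the dye swap shares a preparation with another array. Which array that is, and whether the wild-type RNA was shared between mutants, is not given in the sources used here. Growth conditions and growth stage are also not given there.

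The authors deposited 1 table of log2 ratios with 4116 rows and 12 columns, 1 column per array. The scanner, background correction, normalisation and averaging of spots are not given in the sources used here, and scanner files were not used here. The base of the deposited log2 ratios was settled from the values, many of which are log2 of whole numbers or of multiples of 0.5. The direction was settled, by a rule fixed before the data were examined, from the genes that each mutant lacks. They lay far below 0 on all arrays of the mutants that lack them, dye swaps included, so every column was read as mutant over wild type and no sign was turned. The medians of the deposited columns lay between -0.07 and 0.18, so that any centring by the authors was not exact. The table gives no intensities, so the signal behind a ratio is unknown.

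Many deposited ratios were steps of 0.5 in linear terms (1, 1.5, 2 and so on, or their inverses, within a relative tolerance of 4e-05 and up to a ratio of 100). They are called floor values below and were read as ratios with a channel at its lowest signal. This reading was not tested, because the table gives no intensities. They made up 8.85% to 33.5% of the values of an array, and 1001 genes had at least 3 of them on the 9 arrays with the mutant in Alexa Fluor 647.

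The 10 control features with names of other organisms were left out, which left 4106 genes with 1 row each. Of these names, 3036 are current symbols of the gene table of assembly ASM904v1, and 1070 were kept as the table gives them. That table was used for names and gene order, and no coordinates were taken from it. The mprF gene appears under its older name yfiX, and ywnE is the older name of clsA. The older gene yfiW, beside yfiX, has no entry of its own in the current gene table and was treated with yfiX as part of the mprF locus. This was decided after its values were seen.

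Each array was centred on its median. The 9 arrays with the mutant in Alexa Fluor 647 entered 1 fit with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which estimated each gene's spread over all 3 mutants with 6 residual degrees of freedom and 1.58 prior degrees of freedom. The dye swaps were kept as a check and as alternatives, because they share RNA with the other arrays. The log2 ratio of each mutant was tested against 0, and the differences quadruple minus triple, quadruple minus ugtP, and quadruple minus triple minus ugtP were tested in the same fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Errors of mutant means are SDs over 3 arrays and errors of differences are standard errors from limma. Precision is limited by the number of arrays.

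A set of 35 gene lists was fixed before the data were examined. It covered the SigM, SigW, SigX, SigB and other ECF sigma factor regulons and the LiaRS, peptide transporter and CssRS stress systems. It also covered fatty acid, phospholipid and teichoic acid synthesis, division, flagella, autolysins, heat and cold shock, ribosomal proteins, biofilm, competence, surfactin, cannibalism, antibiotics and sporulation. The SPbeta and PBSX prophages, phosphate, iron, peroxide, zinc, oxygen, carbon, branched-chain amino acid, arginine, pyrimidine and purine lists completed it. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 35 lists. The list tests were repeated with a correlation estimated from the residuals and with fry, which asks whether a list's genes move, on balance, one way. Disrupted genes were left out of lists in the mutants that lack them. Members were also counted after adjustment over the list alone.

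Genes were named by a rule fixed before the data were examined. It took the disrupted genes, then for each mutant up to 12 called genes with the largest mean rise and up to 12 with the largest mean fall that had the same sign on all 3 arrays and on the dye swap. It added up to 4 members with the smallest p of each list that passed, and of the SigM, SigW, SigX, LiaRS, lipid, fatty acid, division and flagella lists in any case. For differences between mutants it took up to 8 called genes per direction, and where fewer than 5 genes were called, the 5 smallest p values were given as values. Genes outside the rule are marked as chosen after their values were seen.

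The procedure was tested on simulated data for the same 4106 genes, with 200 genes changed. For the ugtP mutant it recovered 5.97% of 2-fold, 58.2% of 4-fold and 77.3% of 16-fold changes. For the triple mutant these shares were 13.4%, 52.2% and 80.3%, and for the quadruple mutant 13.4%, 58.2% and 80.3%. False calls made up 3.09%, 9.35% and 5.61% of the calls. In a simulated test of lists for the quadruple mutant, a list shifted by 1 on the log2 scale was called and 0 of 40 random lists were (limma's camera, adjusted p under 0.05). Both simulations drew values independently across genes and arrays, with the same spread of a gene on every array. They therefore cannot show the false calls where genes vary together or arrays differ in spread, as the real ones did. The random lists in particular met the preset correlation by construction.

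Alternatives fixed before the data were examined were the values without centring, quantile normalisation, all 12 arrays without or with a gene-wise dye term, only the arrays of the mutants compared, a block for the replicate number, genes with a value on all 9 arrays, a robust prior, a 2-fold minimum, and leaving out each array. Leaving out floor values, array weights, and leaving out the 3 arrays numbered 3 were added after the spread of the arrays was seen. An alternative for several spots of 1 gene was not run, because each gene had 1 row. The fit of 12 arrays treats a dye swap as an independent array, which makes its p-values too small. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.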

Results

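The series asked how gene expression in Bacillus subtilis changes when the lipids of the cytoplasmic membrane are altered. The ugtP gene encodes the enzyme that adds glucose to diacylglycerol to make glycolipids, mprF the enzyme that makes lysyl-phosphatidylglycerol, pssA phosphatidylserine synthase, and ywnE a cardiolipin synthase. A ugtP mutant, an mprF pssA ywnE triple mutant and a quadruple mutant lacking all 4 genes were each compared with wild type on 3 arrays of 1 dye orientation and on 1 dye swap, 12 arrays in all. Each array gave a log2 ratio of mutant over wild type for 4078 to 4106 genes. The spread of these ratios differed between arrays, with SDs from 0.74 on triple mutant replicate 1 to 2.05 on quadruple mutant replicate 3. Floor values, ratios read as those of a channel at its lowest signal, made up 8.85% of quadruple mutant replicate 1 and 32.8% of triple mutant replicate 3.

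The disrupted genes were low wherever the labels say that they are missing. The ugtP ratio lay between -7.03 and -4.70 on the 8 arrays of the ugtP and quadruple mutants, and between -0.47 and -0.05 on the 4 arrays of the triple mutant. On the 8 arrays of the triple and quadruple mutants, yfiX (the older name of mprF) lay between -10.1 and -6.22, pssA between -9.31 and -2.71, and ywnE between -5.70 and -3.44. On the ugtP mutant's arrays yfiX lay between -0.35 and 0.25, pssA between -0.59 and -0.28 and ywnE between -0.68 and 0.24. The neighbouring older gene yfiW behaved like yfiX, with -7.38 to -4.10 against -0.27 to -0.03. All were called with limma in the mutants that lack them, with adjusted p from 0.00097 to 0.012.

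**Figure D1:**
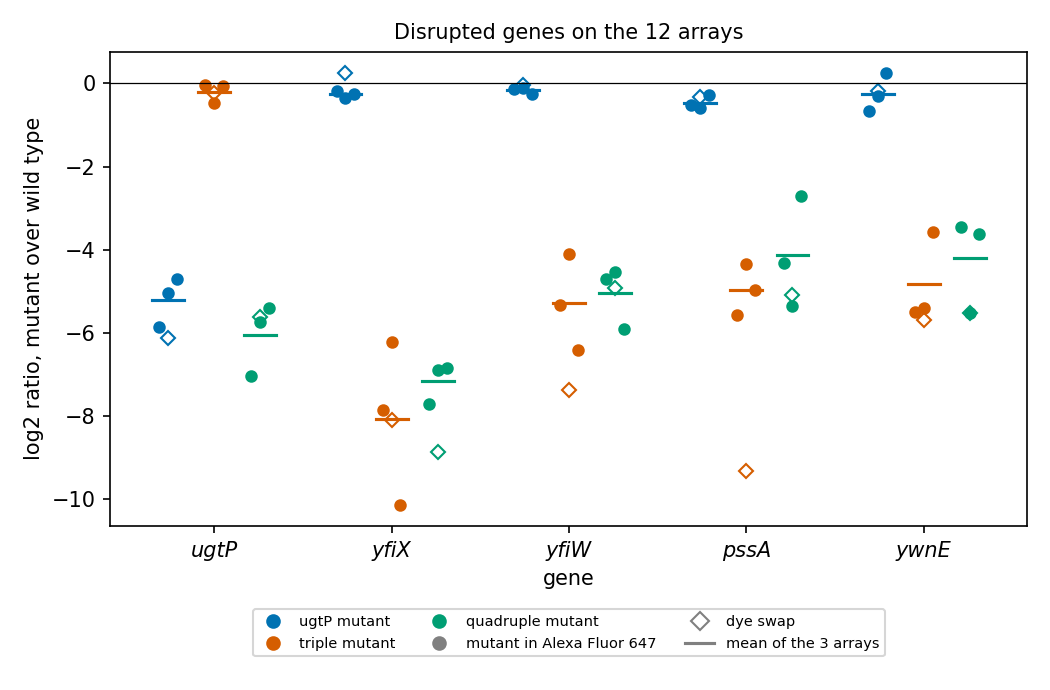
Log2 ratio of mutant over wild type (vertical axis) of the disrupted genes on the 12 arrays, with filled circles for the 3 arrays with the mutant in Alexa Fluor 647, open diamonds for the dye swap and lines for the mean of the 3 arrays. Ratios of ugtP lie at or below -4.70 in the ugtP and quadruple mutants, and those of yfiX, yfiW, pssA and ywnE lie at or below -2.71 in the triple and quadruple mutants.

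The first comparison asked what loss of the glycolipid enzyme alone changes. In the ugtP mutant yqjL, a gene of the SigM regulon, rose to a log2 ratio of 2.21 ± 0.09 (SD, 3 arrays), with 1.28 on the dye swap and a limma adjusted p of 0.020. Besides ugtP itself (-5.21 ± 0.60, adjusted p = 0.0030), ykvO fell to -2.91 ± 0.55 with adjusted p = 0.020, but its dye-swap ratio was -0.29 and 4 of its 9 values were floor values. These 3 genes were the whole of the calls among 4106 genes. An unadjusted limma p under 0.05 was found for 642, where chance would give 205.3 for independent arrays without a dye effect. All 3 arrays had 1 dye orientation, so a gene-specific dye effect can add to the 642. The next smallest p values belonged to yozN, with 3.79 ± 0.74 (adjusted p = 0.050, dye swap 0.04, 5 of 9 floor values), and yckJ, with -1.25 ± 0.10 (adjusted p = 0.057, dye swap -0.32).

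The SigM regulon, which answers to cell envelope stress, rose as a list in the ugtP mutant, with a median of 0.62 over 36 measured members and an adjusted p of 7.1e-08 with limma's camera (adjusted p = 0.40 with an estimated correlation). Of its members 1 rose, none fell and 35 did not pass, and 15 rose when adjusted over the list alone. Besides yqjL, ypbG had 1.58 ± 0.33 (adjusted p = 0.083), the rod-shape gene rodA 1.06 ± 0.17 (0.083) and ywaC, a synthetase of the alarmone ppGpp, 2.02 ± 1.13 (0.10). The SigM medians were 0.76, 0.49 and 0.41 on the 3 arrays and 0.83 on the dye swap. The fatty acid synthesis list fell, with a median of -0.85 over 13 members and adjusted p = 2.5e-07 (adjusted p = 0.31 with an estimated correlation). Among all genes 0 of its members passed, and 8 fell when adjusted over the list alone. Its smallest p values were those of fabD (-1.11 ± 0.12, adjusted p = 0.083), fabG (-1.02 ± 0.12, 0.11), fabHA (-1.04 ± 0.04, 0.14) and plsX (-0.93 ± 0.31, 0.14), and its medians were -0.85, -0.55, -0.82 and, on the dye swap, -0.66. Autolysins, the enzymes that cut the cell wall, also fell as a list of 9 (median -0.76, adjusted p = 0.0016, and adjusted p = 0.46 with an estimated correlation), with 3 members falling when adjusted over the list alone. They were the lytABC operon, with -2.26 ± 0.40 for lytA, -2.37 ± 0.39 for lytB and -2.33 ± 0.41 for lytC (adjusted p = 0.083, 0.083 and 0.062).

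The flagella and chemotaxis list had a median of -0.68 over 42 members in the ugtP mutant (adjusted p = 1.7e-09, and 0.81 with an estimated correlation), 0 members passed, and its dye-swap median was 0.05. The iron list controlled by Fur had a median of -0.64 over 31 members (adjusted p = 2.6e-08, and 0.81 with an estimated correlation) and the SigW regulon -0.47 over 45 (6.3e-07, and 0.81). Surfactin and quorum sensing genes had a median of -0.41 over 13 members (0.0035, and 0.46), with 1 member falling when adjusted over the list alone and comS at -2.10 ± 0.49 (limma adjusted p = 0.14). Purine synthesis had a median of -0.51 (0.030, and 0.85), heat shock -0.43 (0.037, and 0.81), and cell division and shape 0.17 (0.030, and 0.85). In none of these lists did a member pass among all genes. The ugtP dye-swap medians were -0.07 for Fur, 0.21 for SigW and -0.06 for surfactin genes. Those of purine, heat shock and division genes were 0.84, 0.14 and 0.44. On the other arrays of this mutant the purine medians disagreed in sign, with 0.04, -0.44 and -0.80 in replicate order. So did those of heat shock, with -0.48, 0.04 and -0.60. The SPbeta prophage list had a median of 0.998 over 180 members (1.7e-09, and 0.14). Floor values made up 71.2% of its values, its dye-swap median was -0.34, and no member passed.

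Leaving out ugtP replicate 2 ended every call in the ugtP mutant, that of ugtP included, leaving out ugtP replicate 1 gave 11 genes higher, and the call of yqjL ended without any 1 of the 3 ugtP arrays, without triple replicate 1 or without quadruple replicate 2 (adjusted p from 0.053 to 0.21). Across genes the mean of the 3 arrays ran against the dye swap (r = -0.46, and 0.05 over 3028 genes without floor values). With a gene-wise dye term over all 12 arrays 13 genes were higher and 19 lower. On the 9 arrays, array weights gave 25 and 29, and a block for the replicate number 66 and 25. With the dye term the lists of SPbeta, SigW, surfactin, heat shock and purine genes no longer passed. In all 11 lists passed with it, as many as without, so others passed only with it.

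The second comparison asked what loss of mprF, pssA and ywnE changes. In the triple mutant des, the fatty acid desaturase that introduces double bonds into membrane lipids, fell to -3.34 ± 0.49 (adjusted p = 0.0094) with -4.09 on the dye swap. Also lower were pel (pectate lyase) at -2.42 ± 0.55, dctP (dicarboxylate uptake) at -2.28 ± 0.19, and the xylose genes xylB and xylA at -1.76 ± 0.39 and -1.71 ± 0.35, with adjusted p of 0.0099, 0.034, 0.046 and 0.037. Their dye-swap ratios were -1.07, -2.27, -1.29 and -0.91. With yfiX (-8.07 ± 1.97), yfiW (-5.29 ± 1.16), pssA (-4.96 ± 0.61) and ywnE (-4.82 ± 1.08) these were all 9 genes called, each of them lower. No gene was called higher with limma, 314 genes had an unadjusted p under 0.05, and the fit with a dye term called 2 higher and 10 lower.

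Surfactin and quorum sensing genes fell as a list in the triple mutant, with a median of -0.9996 over 13 members and adjusted p = 5.6e-13 (adjusted p = 0.072 with an estimated correlation, 0.0046 with fry). The array medians were -1.04, -1.40 and -0.81, with -0.03 on the dye swap. Among all genes 0 members passed, and 9 fell when adjusted over the list alone. The surfactin synthetase genes srfAA and srfAB had -3.07 ± 1.21 and -3.91 ± 1.19 and the embedded competence gene comS -2.85 ± 1.34 (adjusted p = 0.12 each), with dye-swap ratios of -1.40, 2.39 and -1.41. The SigX regulon fell with a median of -0.55 over 11 members (1.5e-07, and 0.35 with an estimated correlation), with 2 members falling when adjusted over the list alone, and the wall teichoic acid list with -0.40 over 14 (1.1e-04, and 0.40), which had 0.04 on the dye swap and did not pass with a dye term (adjusted p = 0.082). Their shared dltABCD genes, which attach D-alanine to teichoic acids, had ratios from -0.64 for dltA to -0.48 for dltD, none of them called. In the fatty acid list (median -0.22, adjusted p = 0.0042, and 0.40) 1 of 13 members fell, which was des, while fabD had -0.23. This list had 0.31 on the dye swap and did not pass with a dye term (median -0.046, adjusted p = 0.64) or without the arrays numbered 3 (adjusted p = 0.19). Of 37 genes of carbon uptake and use 1 fell, dctP, and that list did not pass (median -0.03, adjusted p = 0.25).

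Flagella and chemotaxis genes had a median of -0.82 in the triple mutant (adjusted p = 1.3e-22, and 0.40 with an estimated correlation) and 0 of 42 passed. The array medians were -0.52, -1.57 and -0.46, with 0.15 on the dye swap. Lower medians also came with ribosomal proteins (-0.25, 4.9e-08, and 0.40), PBSX prophage (-0.59, 2.8e-04, and 0.68), autolysins (-0.70, 7.9e-04, and 0.40), PerR (-0.33, 1.8e-04, and 0.42), Fur (-0.22, 0.0013, and 0.72) and purine genes (-0.40, 0.0040, and 0.65). Cold shock genes (-0.52, 0.020, and 0.40) and division genes (-0.14, 0.021, and 0.68) were also lower as lists. For ribosomal, PerR, Fur, cold shock and division genes the array medians disagreed in sign, reaching 0.01, 0.02, 0.44, 0.28 and 0.07. Their dye-swap medians were 0.68, -0.17, 0.34, 0.39 and 0.25. The purine medians were -0.03, -0.17 and -0.91 on the 3 arrays. Without the arrays numbered 3, PerR, Fur, purine, cold shock and division genes did not pass (adjusted p from 0.090 to 0.38). Higher medians came with the general stress genes of SigB (0.84, 0.0031, and 0.78), SPbeta (0.54, 2.7e-04, and 0.35), the CssRS secretion stress genes (0.52, 0.015, and 0.40) and the other ECF sigma operons (0.42, 0.020, and 0.65). For SPbeta the medians of single arrays were -0.04, 0.52 and -0.07, of which -0.04 and -0.07 are deposited ratios of 1 shifted by the centring. The other ECF operons did not pass without the arrays numbered 3 (adjusted p = 0.15). Arginine synthesis (1.15, 0.020, and 0.65) and zinc genes (0.90, 0.043, and 0.42) also had higher medians, which came from triple replicate 3 alone. Their medians there were 2.10 and 2.24, against values from -0.15 to 0.30 on the other 2 arrays and -3.57 and -1.19 on the dye swap, and neither list passed without the arrays numbered 3 (adjusted p = 0.63 and 0.48). The SigB median came from triple replicate 2, with 2.11 there and 0.30 and -0.68 on the others. No member of any of these lists was called among all genes. On the dye swap the SigB genes ysnF and katX, at 3.62 and 1.96 on the 3 arrays, had -2.25 and -4.73.

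Leaving out triple replicate 1, 2 or 3 left 2, 3 or 5 genes lower and, without the third, 11 lists in place of 19, and without triple replicate 2 the SigB list turned its direction. The mean of the 3 arrays ran against the dye swap (r = -0.51, and -0.11 over 2599 genes without floor values). For the single arrays r was 0.07, -0.07 and, on replicate 3, -0.61. With a dye term 9 lists passed in place of 19. Of the 19, those that passed again in the same direction were SigX, secretion stress, flagella, autolysins, surfactin and PBSX, the ribosomal list turned to higher, 11 did not pass, and cold shock was not tested. The remaining lists that passed with the dye term were not among the 19.

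The third comparison asked what the loss of all 4 genes changes. In the quadruple mutant 134 genes were called, 39 higher and 95 lower, and 131 of them had the same sign on all 3 arrays and on the dye swap. Outside the disrupted genes, 126 of 129 had the same sign on the dye swap. Agreement among the 3 arrays was favoured by the calling itself, and the dye swap shares an RNA preparation with 1 of them. Members of the flagella and chemotaxis list made up 28 of the 95 that were lower. Of 42 measured members of the flagella list these 28 fell, none rose and 14 did not pass, and 41 fell when adjusted over the list alone. The flagellar motor genes motA and motB fell to -4.27 ± 0.98 and -3.95 ± 0.86, the export genes fliR and fliQ to -2.08 ± 0.46 and -1.85 ± 0.37, the sigma factor gene sigD to -1.73 ± 0.18 and cheC to -1.77 ± 0.52 (limma adjusted p from 0.011 to 0.045). The list median was -1.79 (adjusted p = 1e-33, 0.21 with an estimated correlation, 0.0092 with fry), with -1.61, -2.27 and -1.50 on the 3 arrays and -2.16 on the dye swap. The oxygen sensor gene of aerotaxis, hemAT, at -4.33 ± 0.88, and yfmS and yfmT, at -3.81 ± 0.95 and -3.72 ± 0.95, were among the largest falls of called genes outside the lists.

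Autolysins fell with a median of -2.52 over 9 members (adjusted p = 3.2e-08, and 0.17 with an estimated correlation), of which 4 fell and 7 fell when adjusted over the list alone. The genes lytA, lytB and lytC fell to -3.39 ± 0.28, -3.26 ± 0.12 and -2.90 ± 0.36 (adjusted p = 0.0093 each), with -3.38, -3.27 and -3.03 on the dye swap, and the PBSX autolysin xlyA to -1.57 ± 0.11. Of the PBSX prophage list 10 of 30 fell and 21 fell when adjusted over the list alone (median -1.55, adjusted p = 9.5e-14, and 0.47), among them xhlB at -2.36 ± 1.04 and xkdF at -1.93 ± 0.65. The PBSX medians were -2.29, -1.97 and -0.62 on the 3 arrays and -1.80 on the dye swap. Those of the ugtP and triple mutants ran from -1.19 (ugtP dye swap) to 0.21 (ugtP replicate 3), so the ranges overlapped. In the fatty acid list 3 of 13 fell, and 8 when adjusted over the list alone (median -0.81, adjusted p = 6e-07, and 0.17). They were des at -3.83 ± 0.32, fabI at -1.18 ± 0.36 and fabD at -1.06 ± 0.38, with -3.70, -1.27 and -1.22 on the dye swap. Of 13 surfactin and quorum sensing genes 2 fell, and 4 when adjusted over the list alone (median -0.55, adjusted p = 7.7e-05, and 0.18), with srfAA at -3.39 ± 1.02 and comS at -2.53 ± 0.63.

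**Figure D2:**
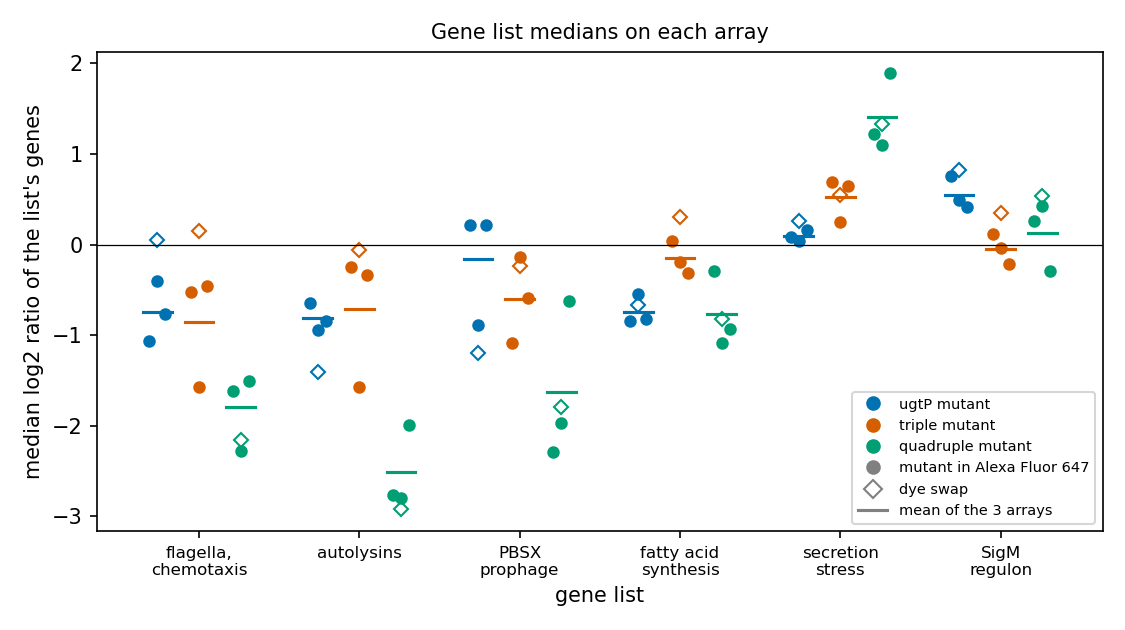
Median log2 ratio of mutant over wild type (vertical axis) of 6 gene lists on each array, with filled circles for the 3 arrays with the mutant in Alexa Fluor 647, open diamonds for the dye swap and lines for the mean of the 3 medians. The flagella medians of the quadruple mutant lie between -2.27 and -1.50, dye swap included, while those of the ugtP and triple mutants reach 0.05 and 0.15 on their dye swaps.

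The secretion stress genes controlled by CssRS rose in the quadruple mutant, with 2 of 4 called, all 4 when adjusted over the list alone, and a median of 1.503 (adjusted p = 1.5e-05, 0.17 with an estimated correlation, 0.0011 with fry). The membrane protease genes htrA and yvtA rose to 1.80 ± 0.24 and 1.64 ± 0.26 (adjusted p = 0.010 and 0.012), with 1.66 and 1.83 on the dye swap, and cssR and cssS had 1.37 ± 0.84 and 0.81 ± 0.31 (0.064 each). The cell shape gene mreBH rose to 1.93 ± 1.17 (adjusted p = 0.048), 1 of 19 members of a list that did not pass. Among called genes with the same sign on all 3 arrays and on the dye swap, the largest rises were those of yrkN (6.26 ± 2.34), yrkO (6.25 ± 2.85), yfjC (5.34 ± 2.28), yfjB (5.15 ± 1.81), the biofilm coat gene yuaB (4.19 ± 2.28) and yxiC (4.15 ± 1.62), all between 3.95 and 4.77 on the dye swap. They were followed by yukC (4.05 ± 1.92), yjhA (3.41 ± 0.54), ywqI (3.29 ± 0.57), yukA (3.07 ± 0.16) and yueB (3.06 ± 0.67). The alcohol dehydrogenase gene adhB rose to 4.19 ± 0.88 with 1.78 on the dye swap, and all 9 of its values were floor values.

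Other large falls of called genes in the quadruple mutant were those of yveM (-4.25 ± 0.81) and yveL (-3.93 ± 1.98), of the biofilm exopolysaccharide operon, of ykoW (-3.93 ± 0.56), and of yqjN (-3.64 ± 0.51, dye swap -0.96, 6 of 9 floor values). In the Fur list (median -0.45, adjusted p = 2.8e-04, and 0.87 with an estimated correlation) 1 of 31 members fell, yfiY, which lies beside mprF, at -1.66 ± 0.38. The SPbeta list (median 0.73 over 180 members, adjusted p = 7.6e-06, and 0.17) held 2 called members, yorE at 2.40 ± 0.75 and yokF at 2.01 ± 0.54, with dye-swap ratios of -2.17 and 0.36. Ribosomal proteins had a median of -0.21 (0.012, and 0.87) and heat shock genes -0.31 (0.043, and 0.87), with no member called. Neither passed with a dye term (adjusted p = 0.31, with the ribosomal median at 0.047, and 0.19), without floor values (adjusted p = 0.36 and 0.17) or without the arrays numbered 3 (adjusted p = 0.48 and 0.21), and SPbeta did not pass with a dye term (adjusted p = 0.82). The SigM regulon, with a median of 0.16 over 36 members, did not pass (adjusted p = 0.24), and its yqjL had 1.03 ± 0.51 (0.055). It passed with a dye term (median 0.31, adjusted p = 2.1e-04) and without the arrays numbered 3 (0.31, adjusted p = 0.0035). Division, PerR and purine genes, which did not pass either, also passed with a dye term (adjusted p = 0.0098, 0.027 and 0.0016). With an estimated correlation none of these 4 lists passed on the 9 arrays (adjusted p from 0.87 to 0.996).

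**Figure D3:**
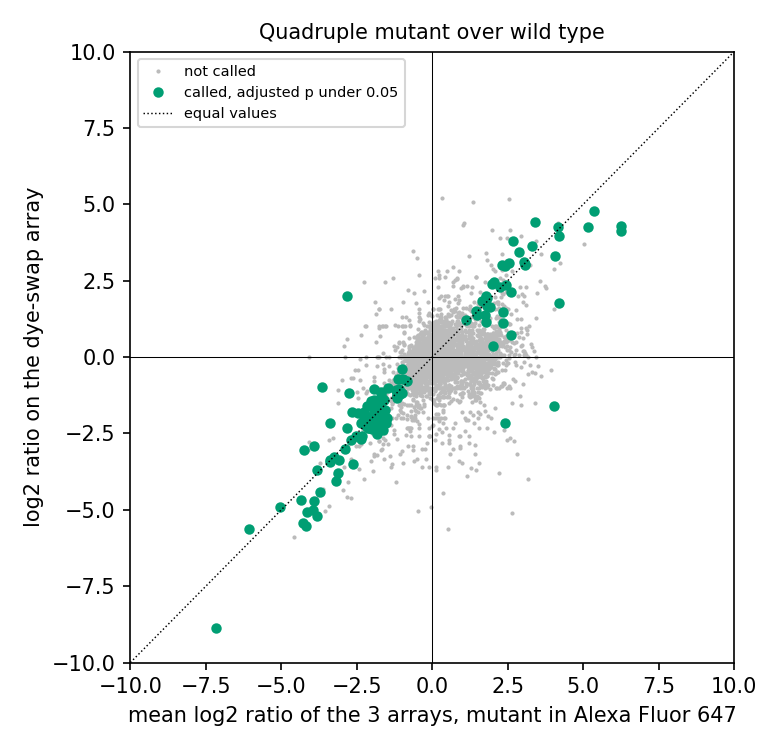
Log2 ratio of quadruple mutant over wild type for each gene, as the mean of the 3 arrays with the mutant in Alexa Fluor 647 (horizontal axis) and on the dye-swap array (vertical axis), with called genes in green and the dotted line at equal values. Outside the disrupted genes, 126 of 129 called genes had the same sign on both axes.

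The lists that passed in no comparison had medians between -0.28 and 0.75 in the quadruple mutant. They were LiaRS (0.02), peptide transporters (-0.18), phospholipid and lipoteichoic acid synthesis (-0.22), biofilm (-0.17), competence (-0.04), cannibalism (-0.28), antibiotic synthesis (0.75), early sporulation (0.51), phosphate (0.22), oxygen limitation (-0.27), branched-chain amino acids (-0.05) and pyrimidines (-0.05). Their adjusted p in the quadruple mutant ran from 0.19 to 0.98. For oxygen limitation the arrays disagreed, with medians of -0.20, -1.20 and, on replicate 3, 2.54, and with -0.56 on the dye swap. In the phospholipid list no remaining member passed, with pgsA at 0.67 ± 0.35 and plsX at -0.94 ± 0.38 (limma adjusted p = 0.32 and 0.068). Median, mean and test had the same sign in each list that passed. In the quadruple mutant they differed in sign for oxygen limitation (-0.27, 0.36, up), carbon use (-0.01, 0.40, up), other ECF operons (-0.06, 0.26, up), division (-0.03, 0.07, up), pyrimidines (-0.05, -0.07, up) and LiaRS (0.02, 0.05, down).

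Without quadruple replicate 1, 2 or 3 the calls fell to 0, 3 or 6 higher and 1, 4 or 6 lower, and without ugtP replicate 1, 2 or 3, whose values enter only the common spread, to 11, 22 or 24 higher and 25, 49 or 33 lower (27 and 56 without triple replicate 1). Quantile normalisation gave 18 higher and 16 lower, array weights 33 and 63, and the values without centring 49 higher and 83 lower. A block for the replicate number gave 126 higher and 112 lower.

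The difference between the quadruple and triple mutants asked what loss of ugtP adds to loss of the other 3 genes. Only 2 genes were called, ugtP itself at -5.86 (standard error 0.50, adjusted p = 0.016) and yhjN at -2.56 (0.28, adjusted p = 0.044). The lytABC genes had -2.69 for lytA, -2.68 for lytB and -2.18 for lytC (adjusted p = 0.54 each), adhB had 4.06 (0.27) and yvbI -2.01 (0.54). As lists, flagella (median -1.02, adjusted p = 1e-15), PBSX (-1.12, 8.8e-11), autolysins (-1.30, 1.2e-06), fatty acid synthesis (-0.56, 1.4e-04) and heat shock genes (-0.33, 0.023) were lower in the quadruple mutant. Secretion stress (0.98, 2.6e-05), PerR (0.49, 4.2e-05), purine (0.74, 4.9e-05), SigX (0.45, 1.3e-04), carbon use (0.21, 0.017), surfactin (0.32, 0.022), SigM (0.17, 0.026) and teichoic acid genes (0.28, 0.026) were higher. With an estimated correlation none of these 13 lists passed (adjusted p from 0.28 to 0.64). Leaving out any 1 of the 9 arrays ended the call of yhjN (adjusted p from 0.072 to 0.28), and 8 lists passed without triple replicate 3. The fit with a dye term called 6 genes, and in it the surfactin (median -0.05, adjusted p = 0.34) and teichoic acid lists (adjusted p = 0.071) did not pass. Surfactin did not pass without floor values either (adjusted p = 0.11). Without the arrays numbered 3 heat shock, purine, carbon use, surfactin and teichoic acid genes did not pass, and the purine median was 0.24 (adjusted p = 0.14).

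The difference between the quadruple and ugtP mutants asked what loss of the other 3 genes adds to loss of ugtP. With limma 0 of 4106 genes were called, although yfiW and yfiX, which only the quadruple mutant of this pair lacks, had -4.88 (standard error 0.62) and -6.89 (0.88, adjusted p = 0.14 each). At an unadjusted p under 0.05 there were 201 genes, where chance would give 205.3 for independent arrays, and the fit with a dye term called 7. The next values were yrkR at 2.72, ykvO at 2.49 and htrA at 1.81 (adjusted p = 0.28 each). Lists lower in the quadruple mutant were flagella (median -1.12, adjusted p = 1.4e-25), PBSX (-1.46, 4.1e-18), SigM (-0.45, 2.6e-06), autolysins (-1.13, 2.5e-05), division (-0.20, 0.021) and teichoic acid genes (-0.27, 0.021). Secretion stress (1.41, 3.3e-08), SigW (0.32, 1.1e-05), purine (0.82, 5e-05) and carbon use genes (0.21, 0.0019) were higher. None of these 10 lists passed with an estimated correlation (adjusted p from 0.17 to 0.84), and secretion stress also passed with fry (0.0087). Carbon use did not pass with a dye term (adjusted p = 0.059), nor teichoic acid and division genes without floor values (adjusted p = 0.093 and 0.057), nor these 2 and purine without the arrays numbered 3 (adjusted p = 0.21, 0.82 and 0.053).

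The departure of the quadruple mutant from the sum of the ugtP and triple mutants' log2 changes was called for 0 genes with limma and with a dye term. An unadjusted p under 0.05 was found for 131 genes, where chance would give 205.3 for independent arrays. The smallest p values belonged to yolD (3.93), yhjN (-1.78), ytpQ (3.25), yrhB (4.13) and spoVB (-4.32), each with adjusted p = 0.998. Lists with a departure above the sum were purine (median 1.19, adjusted p = 5.7e-08), surfactin (0.75, 5.1e-07), PerR (0.61, 7.8e-06), secretion stress (0.88, 6.9e-05), SigX (0.50, 6.9e-05), Fur (0.37, 6.9e-05), carbon use (0.53, 6.9e-05), ribosomal (0.26, 1.6e-04) and SigW genes (0.30, 0.0011). Those below it were PBSX (-0.89, 2.5e-07), SPbeta (-0.76, 1.4e-04) and SigM (-0.38, 5.0e-04). With an estimated correlation the adjusted p of these 12 lists ran from 0.33 to 0.71. At least 12 lists were called by 57 of 100 groupings of the 9 arrays, the real one among them. A change common to the mutants stays in this difference when the arrays are regrouped. A gene-specific dye effect common to the 3 mutants does not cancel in this difference, and with a dye term the ribosomal, SigW and SPbeta medians were -0.22, -0.15 and 0.17. SPbeta, SigX, Fur and PerR did not pass with it (adjusted p = 0.76, 0.15, 0.76 and 0.092), and SigW did not without the arrays numbered 3 (adjusted p = 0.16).

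The triple and quadruple mutants shared 8 called genes, each lower in both: des, pel, xylA, xylB and the disrupted yfiX, yfiW, pssA and ywnE, which the design lowers in both. Independent lists of these sizes would share 0.208 genes, and unchanged mutants with a shared wild-type value shared 0.02 in 100 simulations, or 0.61 with a shared dye effect added. The disrupted genes were counted in the lists behind the 0.208, and the simulated mutants lacked no gene. Only des, pel, xylA and xylB therefore bear on these values, and no expected count was computed for calls without the disrupted genes. The ugtP and quadruple mutants shared ugtP and no other gene, and the ugtP and triple mutants shared none. With a gene-wise dye term over 12 arrays these pairs shared 21 genes (6 higher and 15 lower) and 1 gene, and the triple and quadruple mutants 11. Across genes, the log2 ratios correlated with r = 0.61 between triple and quadruple, 0.61 between ugtP and quadruple and 0.49 between ugtP and triple, where genes are not independent replicates. Simulated unchanged mutants gave 0.493, 0.496 and 0.495 from a shared wild-type value, and 0.685, 0.683 and 0.682 with a shared dye effect added. The covariances were 0.555, 0.690 and 0.417, against 0.225, 0.227 and 0.227 with shared wild type and 0.5023, 0.4997 and 0.4997 with the dye effect. With the dye term the correlations were 0.22, 0.29 and 0.28. Since the correlations were lower with the dye term, a dye effect common to the mutants may account for part of them. Part of the correlations and of the overlap may also come from wild-type RNA shared between the mutants. These sources could not be split.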

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

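All tests of technical and biological explanations given here were chosen after the results were seen, and only the counts over other splits of the arrays were chosen before.

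The mutants differed from each other in 2 named genes and, at a preset correlation, in several gene lists. The quadruple mutant lay below the triple mutant by a log2 difference of -5.86 for ugtP, which only the quadruple mutant of the pair lacks, and of -2.56 for yhjN. The call of yhjN ended when any 1 of the 9 arrays was left out. The yhjN means were -0.78 in the ugtP mutant, 0.95 in the triple mutant and -1.61 in the quadruple mutant. Lists past the threshold numbered 13 for quadruple minus triple, 10 for quadruple minus ugtP and 12 for quadruple minus triple minus ugtP, and 0 in each with an estimated correlation.

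Other groupings of the arrays set a limit to these counts. Turning the signs of the 3 arrays of a mutant gives 4 groupings, too few for a share under 0.05. In each mutant only 1 of the 4, the real one, called as many genes (3, 9 and 134, against at most 0 otherwise). The 10 splits of 6 arrays are also too few. For quadruple minus triple, 3 of 10 splits called as many genes (2 really, 6 at most otherwise) and 1 of 10 as many lists (13 really, 12 at most otherwise). For quadruple minus ugtP, 10 of 10 splits called as many genes (0 really, 10 at most otherwise), which has no bearing on chance, because any split reaches 0. As many lists were called by 3 of 10 splits (10 really, 12 at most otherwise). For quadruple minus triple minus ugtP, 100 of 100 groupings, the real one among them, called at least the 0 genes found (199 at most otherwise). At least the 12 lists found were called by 57 of 100 (18 at most otherwise). By the share of 0.05 set beforehand, both counts had the outcome set for chance. They have no bearing on chance all the same, and nothing was drawn from them. A count of 0 is always reached, and a change common to the mutants stays in this difference when the arrays are regrouped.

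The 10 control features, named after Escherichia coli and brome mosaic virus and used in no comparison, had medians below 0 on all 3 dye swaps, with -1.73 on that of the triple mutant as the lowest. On the 9 arrays with the mutant in Alexa Fluor 647 their median reached 2.51 on quadruple mutant replicate 3, and it lay below 0 on 3 of them (-0.10, -0.27 and -0.32). These features were read as signals outside the main measurement, and no biological explanation was tested for them.

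Flagella and chemotaxis genes were lower in the quadruple mutant with a list median of -1.79. A gene-specific dye bias is argued against by the dye swap, whose list median was -2.16, and floor values by the median without them, which stayed at -1.79. A growth state peculiar to single cultures stays open, because triple mutant replicate 2 had a list median of -1.57, inside the range of the quadruple arrays, while the other arrays of the ugtP and triple mutants lay above it. An effect of the combined loss of ugtP, mprF, pssA and ywnE on motility genes also stays open, as untested.

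On the means of the 3 arrays, the SPbeta prophage list had medians above 0 in all 3 mutants (0.998, 0.54 and 0.73). In the triple mutant the medians of single arrays were -0.04, 0.52 and -0.07, with 0.07 on the dye swap. Apart from 0.52 these are deposited ratios of 1 shifted by the centring, so their signs show no direction. A dye bias of features near the signal floor may account for part of the higher list medians. On the same arrays 840 other genes with at least 3 floor values had medians of 1.44, 0.60 and 0.96, and -1.07, -0.43 and -0.08 on the dye swaps. Without floor values the 29 members left still had medians of 0.62, 0.23 and 0.36 (camera adjusted p = 6.2e-06, 0.040 and 0.018 at the preset correlation). An estimated correlation was run only for the full list with floor values, which then passed in no mutant (camera adjusted p = 0.14, 0.35 and 0.17). Whether floor values account for all of the higher list medians therefore stays open. A rise of prophage genes through the mutations cannot be told apart from a dye bias. In 2 of the 3 mutants, ugtP and quadruple, the dye-swap median of the list lay below all 3 other arrays (-0.34 and -0.21). In the triple mutant it did not, but there the order of the medians rests on centring offsets and cannot decide. With a gene-wise dye term the list medians were -0.02, -0.11 and 0.04.

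In the ugtP and triple mutants the dye swap ran against the mean of the other arrays, with r = -0.46 and -0.51 across genes. With single arrays of the triple mutant r was 0.07, -0.07 and -0.61, so there it was mainly replicate 3 that ran against the dye swap. Floor values could account for most of the negative correlations with the mean, since without floor values these were 0.05 and -0.11. A dye swap stored as wild type over mutant is argued against, because the disrupted genes lay at -4.92 or lower on the dye swaps of the mutants that lack them. In the quadruple mutant r was 0.45, and 0.73 without floor values.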

How the results depend on the processing

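The alternatives without floor values, with array weights and without the 3 arrays numbered 3 were chosen after seeing the data, and all others before. Counts of called genes are given in the order ugtP mutant higher and lower, triple mutant higher and lower, quadruple mutant higher and lower, then the differences quadruple minus triple, quadruple minus ugtP, and quadruple minus triple minus ugtP. The reported counts were 1, 2, 0, 9, 39, 95, 2, 0 and 0. Unless a construction is named, the cause of a change was not tested. No named gene that was called reversed its direction under any alternative run. The call counts stayed close with a minimum change of 2-fold (1, 2, 0, 9, 39, 91, 2, 0, 0), without centring (1, 2, 0, 7, 49, 83, 2, 0, 0), with a robust prior (1, 2, 0, 8, 38, 89, 1, 0, 0) and over the 4017 genes with a value on all 9 arrays (2, 2, 0, 9, 40, 100, 2, 0, 0).

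Quantile normalisation gave 1, 1, 3, 13, 18, 16, 0, 2 and 0. The 12 arrays gave 11, 21, 5, 10, 64, 158, 2, 7 and 0 without a dye term, and 13, 19, 2, 10, 58, 142, 6, 7 and 0 with a gene-wise dye term, with 3 more arrays in the fit. Fits to the arrays of the mutants compared alone, with fewer degrees of freedom, gave 0, 0, 0, 0, 0, 0, 0 and 1. Without floor values 3265 genes were tested and the counts were 5, 13, 3, 13, 56, 142, 2, 2 and 0. Array weights gave 25, 29, 2, 11, 33, 63, 2, 0 and 0. Without the 3 arrays numbered 3, which leaves fewer samples, they were 0, 0, 0, 0, 1, 4, 0, 0 and 0. With a replicate block they were 66, 25, 4, 8, 126, 112, 1, 0 and 0. Same-number arrays of different mutants tended to vary together, since 8 of 9 such pairs correlated above 0.1 (from 0.016 to 0.48), those of the arrays numbered 3 at 0.30, 0.42 and 0.48. The rule fixed for pairing asked for every pair above 0.1 and was not met, so the arrays were not treated as paired. Still, 12 of 18 choices were matched best by the same number, so an effect shared by same-number arrays stays open. What such arrays share is not given in the sources used here.

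Leaving out 1 array gave 0 to 11 higher and 0 to 4 lower in the ugtP mutant, 0 to 1 and 2 to 7 in the triple mutant, and 0 to 36 and 1 to 111 in the quadruple mutant. The differences gave 0 to 1 each. A mutant left with 2 arrays is assumed to vary like the others.

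Gene lists passed in 11, 19, 10, 13, 10 and 12 cases, in the order of the comparisons. With camera's estimated correlation 0 passed in each, and with fry 3, 2, 7, 0, 1 and 0. With the dye term 11, 9, 11, 14, 13 and 14 passed, with the replicate block 11, 17, 10, 14, 11 and 12, without floor values 9, 15, 8, 12, 8 and 13, and without the arrays numbered 3 11, 11, 11, 11, 8 and 14. Leaving out 1 array gave 10 to 14, 11 to 19, 9 to 12, 8 to 16, 9 to 12 and 12 to 16. Lists against wild type that reversed with the dye term are given with their unadjusted camera p values. They were purine synthesis in the ugtP mutant (0.503), division (0.459), ribosomal proteins (0.00111), SPbeta (0.303), Fur (0.998) and arginine synthesis (0.104) in the triple mutant, and ribosomal proteins in the quadruple mutant (0.139). In quadruple minus triple minus ugtP the SigW, ribosomal and SPbeta lists also reversed (medians -0.15, -0.22 and 0.17 with the dye term). The SigB list in the triple mutant ran from 3.2e-10 without triple replicate 3 to 0.635 without triple replicate 2, where it reversed. Shared calls between ugtP and triple, ugtP and quadruple, and triple and quadruple numbered 0, 1 and 8, with the dye term 1, 21 and 11, and without centring 0, 2 and 6. The signal behind the ratios is unknown.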

Other observations

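The operons described here were picked after their values were seen, as was the test of yqxM, sipW and tasA, while the list of DegU activated genes was written before its result was seen. No p-values are given for the operons, because they were picked by their size. Besides the fixed lists, several neighbouring genes moved together. The 8 genes of the yuk and yue operon, which encodes a type VII secretion system, all rose in the quadruple mutant (median 2.95, dye swap 3.04). Their medians were 0.61 in the ugtP mutant and 1.20 in the triple mutant with 0 called, and quadruple minus ugtP had 2.09. Of the toxin operon ywqH to ywqL, 4 of 5 genes rose (median 2.05, dye swap 2.45), of yfjA to yfjF 2 of 6 (3.90, dye swap 2.58) and of yxiB to yxiD 2 of 3 (4.15, dye swap 3.70). The medians of these 3 operons were 0.92, 1.20 and 1.51 in the ugtP mutant (dye swap 0.83, -0.61 and 1.87) and 1.08, 2.30 and 1.44 in the triple mutant (dye swap 0.18, -3.06 and -0.28), with 0 called. Floor values made up 18.5% of the values of yfjA to yfjF.

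The eps operon for the biofilm exopolysaccharide appears under its older names yveK to yveT and yvfA to yvfF, so the fixed biofilm list held only 5 measured genes. In the ugtP mutant all 16 eps genes were below 0 on the mean of the 3 arrays and on the dye swap, with a median of -2.05 and a dye-swap median of -3.06. None was called among all genes, and 5 were with a dye term. In the quadruple mutant 5 of 16 fell (median -1.76, dye swap -2.66), and in the triple mutant the median was -0.11. The difference between quadruple and triple mutants was -1.72. The genes yrkN to yrkS had medians of 2.93 in the quadruple mutant (4 of 6 rose, dye swap 2.57), 2.48 in the triple mutant (0 called, dye swap 1.20) and -0.11 in the ugtP mutant. The opuC operon, for uptake of osmoprotectants, had 1.46 in the triple mutant (dye swap 1.07), 1.17 in the quadruple mutant and 0.03 in the ugtP mutant, with 0 of 4 genes called in each.

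Higher activity of the response regulator DegU was put forward as a hypothesis for genes higher in the quadruple mutant. The DegU activated genes had a median of 1.43 there (limma's camera, n = 14 genes, p = 0.0036), the outcome the hypothesis asked for. The test leaves it open, because p was 0.16 with an estimated correlation, the dye-swap median was 0.14, and the triple mutant gave p = 0.0017 with a dye-swap median of -2.36, while 23.0% of the values of these genes were floor values.

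A regulator shared with the biofilm operon of yqxM, sipW and tasA could account for the lower eps genes in the ugtP mutant. These 3 genes had a median of -1.67 on the 3 arrays and of -1.50 with a gene-wise dye term, below the -1 set for the test. That mark was set after their values were seen, so meeting it adds little. Their medians were -1.82 in the quadruple mutant (dye swap -1.50) and -0.73 in the triple mutant (dye swap 0.39). The support is weak, since 0 of the 3 genes were called, yqxM itself had -0.44, and with an estimated correlation camera did not separate the 3 from other genes.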
